A study of Mus musculus with 18 samples.

How the data were processed

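Mouse androgenetic, gynogenetic and fertilized blastocysts were analysed with 3 samples of each kind, and each sample was hybridized to both chips of the Affymetrix MOE430 pair (18 arrays). Per the labels' protocols, embryos were cultured in KSOM medium, RNA was amplified by the Brady and Iscove method, and biotin-labelled cRNA was made by the Affymetrix protocol. The intensity values that the authors deposited are MAS5 signals per probe set on a linear scale, per the submitters' processing notes, which state neither a version of MAS5 nor a target intensity. Because the 2% trimmed mean differed between arrays by up to 1.62 times on chip A and 1.76 times on chip B, the deposited signals were taken as not scaled to a common target. The highest signal was 15550 on chip A and 13650 on chip B.

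Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The plan kept the authors' scaling if the signals proved to be scaled. Since they were not, quantile normalization over the 9 arrays of a chip, which the plan held as an alternative, became the reported setting. The unscaled signals, a common trimmed mean and list tests on chip B were added after seeing the data. A pseudocount of 11 on chip A and 6 on chip B, the 20th percentile of the deposited values, was added before taking log2. Of 22690 and 22575 probe sets, 64 control probe sets on each chip were left out, and probe sets with a mean under the 25th percentile of the chip were removed, which left 16969 and 16883.

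Each chip was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 1 mean per kind of embryo over 9 arrays, 6 residual degrees of freedom and 3.46 and 4.29 prior degrees of freedom). The 3 contrasts and a moderated F test were adjusted by Benjamini-Hochberg within chip and contrast at 0.05. All tests of contrasts were two-sided. An exact permutation test of 3 samples against 3 cannot give a p under 0.1, so limma's adjusted p, which borrows the spread across probe sets, was used. Labels were read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

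Probe sets were named by the symbol of the platform table, and chromosomes came from the mouse annotation of build GRCm38.p6. The files name no build for the probes, so no coordinates are given. On chip A 20393 probe sets had 1 symbol, 691 several and 1606 none, and on chip B 14674, 245 and 7656. Symbols of 20364 and 14499 of the probe sets with 1 symbol were found in the annotation. Only probe sets with 1 symbol entered lists or were named, so H19 and Snurf, whose probe sets carry another symbol as well, were not tested by list.

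Gene lists came from general knowledge: paternally and maternally expressed imprinted genes, genes with paternal expression under maternal H3K27me3, X-linked and Y-linked genes, X inactivation RNAs, inner cell mass and epiblast, trophectoderm, trophoblast differentiation, primitive endoderm, oocyte, genes activated at the first cleavage stage, cumulus, somatic and blood cells, glycolysis, oxidative phosphorylation, ribosomal proteins, p53 targets and apoptosis, cell cycle, unfolded protein and amino acid response, heat shock and oxidative stress, cholesterol synthesis, junctions and cavitation, feedback genes of FGF and MAPK, and imprint maintenance and chromatin. The X-linked list held every gene that the annotation places on X. The 22 lists with at least 5 measured members were tested on chip A with limma's camera at a preset correlation of 0.01, each gene being represented by its probe set of highest mean (10142 genes), with Benjamini-Hochberg adjustment over lists within a contrast. Members carried only by chip B were counted from that chip.

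Named genes were, for each contrast, up to 8 in each direction on chip A and 3 on chip B with the largest change among called probe sets whose groups did not overlap and whose higher group lay at or above the chip's median. Where fewer than 3 passed in a direction, the 3 with the largest moderated statistic were named as not passing. Imprinted genes past the threshold were added, or else the 2 of each list with the largest statistic, as were up to 4 members of each other list whose test passed, and Xist, Ddx3y and Eif2s3y. Ddx3y had no probe set with a single symbol. Other genes, among them further members of the imprinted and H3K27me3 lists, Mest, Clcn5, Cox7b2 and the lists' members found when adjusted over the list alone, were named after their values were seen.

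The alternatives were median centring, the unscaled signals, a common trimmed mean, pseudocounts of 1 and of the median (58 and 22), no filter and a filter at the 50th percentile, the replicate number or the fluidics station as a block, a fit of only the 2 groups compared, no intensity trend, array weights, camera with an estimated correlation, fry, the mean of a gene's probe sets, and leaving out each sample in turn. Fluidics stations and runs were read from the scanner's experiment records. On chip A station 1 held the 3 androgenetic samples, gynogenetic replicate 1 and fertilized replicate 3, and on chip B station 1 held the 3 androgenetic samples and gynogenetic replicate 1. All other arrays were on station 2, and fertilized replicate 3 was hybridized in a later run on both chips.

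The arrays of a sample were checked by the 100 probe sets present on both chips. The Pearson correlation across those probe sets was 0.979 or more between the arrays of the same title, and in each array it exceeded that with every other title. The highest correlation of signals between 2 arrays of a chip was 0.984 on chip A and 0.9708 on chip B, so no array's values copied another's. The procedure was tested on simulated data, with 200 changed probe sets of 3 against 3 samples in 5 runs. Changes of 1, 2, 4 and 6 on the log2 scale were recovered in 6, 26.8, 88 and 97.6% of cases on chip A and in 0.8, 32, 95.2 and 99.2% on chip B, with 6.4 and 3.8 false calls per run and none without changed genes. The runs gave 115.6 and 117.4 calls on average, against 24 and 9 in androgenetic against gynogenetic embryos. The adjusted threshold is stricter with fewer calls, so these rates may be too high for the measured data. Camera called 20 of 20 lists of 20 genes shifted by 1 and 0 of 20 unshifted lists. Smaller shifts were not simulated, and no correlation between the members of a list was simulated. The result therefore does not cover false calls in lists whose members vary together. In the measured lists the estimated correlation was 0.587 for oocyte genes and 0.153 for cholesterol synthesis, but 0.016 for X-linked genes. Image files were not analysed here.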

Results

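Gene expression was measured in 3 kinds of mouse blastocyst, the embryo at the stage of a fluid-filled cavity, an inner cell mass and an outer trophectoderm. Androgenetic embryos hold only paternal genomes, gynogenetic embryos only maternal genomes, and fertilized embryos hold a genome from each parent. Transcripts of imprinted genes are read mainly from the allele of one parent. Where an imprint acts in the blastocyst, they are therefore expected mainly from one of the uniparental kinds. Whether it acts at this stage was not tested for the listed genes. The comparisons ask which transcripts depend on the parental origin of the genome. Gynogenetic embryos hold no Y chromosome, while the other kinds can hold one, so X-linked transcripts can also differ by the number of X chromosomes. Each kind was represented by 3 samples, and every sample was hybridized to both chips of the Affymetrix MOE430 pair, called chip A and chip B here, so that 18 arrays were compared. The 2% trimmed mean signal lay between 330 and 535.7 on chip A and between 38.45 and 67.86 on chip B. Signals above 100 were read on 33.9 to 44.5% of the probe sets of chip A and on 9.76 to 17.1% of those of chip B, and the number of arrays limits the precision of every value. The labels do not say whether the 3 samples of a kind came from separate cultures or pools, so the p-values measure only the spread between these samples, which may be technical.

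Fertilized replicate 3 stood apart from the other samples, and this bears on both comparisons with fertilized embryos. Gdf9, a growth factor secreted by the oocyte, had a signal of 8660 in that sample against 54.8 and 68.9 in fertilized replicates 1 and 2. Tle6 and Nlrp5, parts of the maternal complex beneath the oocyte membrane, reached 5740 and 5320 there, and Zp3, a protein of the zona pellucida, reached 5090. Of the 15 measured members of the oocyte list, 13 were higher by more than 1 on the log2 scale than the mean of the other fertilized samples, with a list median of 4.17. The actin control probe sets gave a ratio of 3′ to middle signal of 10.8 on chip A and 11.7 on chip B in that sample, against 1.86 to 2.99 and 1.94 to 3.13 elsewhere. Their ratio of 3′ to 5′ signal was 93.8 and 110 in that sample, but also 95.5 and 108 in gynogenetic replicate 3. The Gapdh controls had a ratio of 3′ to middle signal of 2.51 and 2.88 in fertilized replicate 3, against 2.48 and 2.68 in androgenetic replicate 3. The median Spearman correlation of fertilized replicate 3 with the other arrays was 0.71 on chip A, where the others had 0.788 to 0.885.

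**Figure D1:**
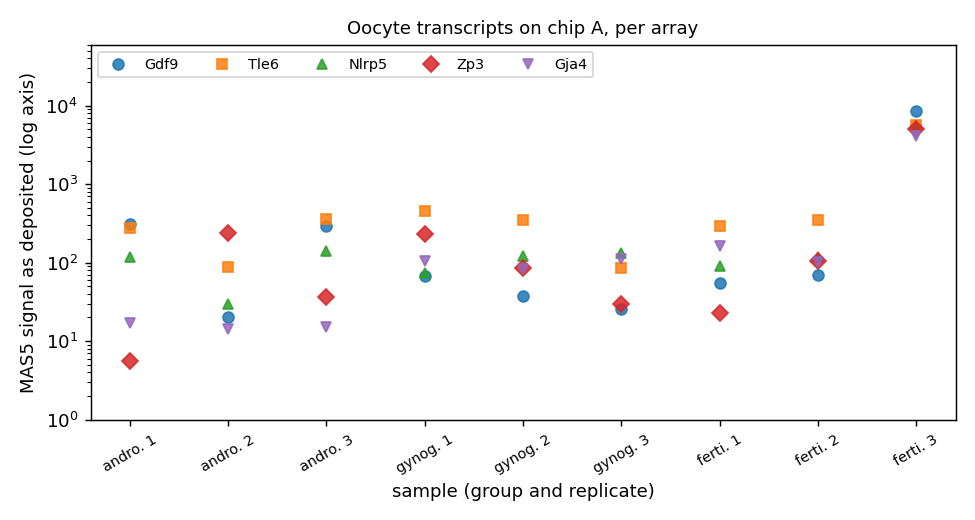
Deposited MAS5 signal (log axis) of 5 oocyte transcripts on chip A in each of the 9 samples, 1 symbol per gene. In fertilized replicate 3 the lowest of the 5, Gja4, is at 4130, and Gdf9 is at 54.8 and 68.9 in the other fertilized samples.

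Gynogenetic embryos were compared with fertilized embryos first, to find transcripts that depend on a paternal genome. Slc38a4, a transporter of neutral amino acids, fell by 6.68 ± 0.54 on the log2 scale (SE, n = 3 and 3), with a limma adjusted p of 0.00679. Its mean signal was 6.43 in gynogenetic and 1950 in fertilized embryos. Since the lower signal lies under the pseudocount of 11, the size of the change depends on that choice, and it ran from −8.10 to −4.78 over other scalings, pseudocounts and blocks. Sfmbt2, a Polycomb group protein needed in the trophoblast, fell by 5.27 ± 0.51 (adjusted p = 0.016), and Plagl1, an imprinted zinc finger transcription factor, fell by 5.69 ± 0.60 (adjusted p = 0.0218). On chip B the long noncoding RNA Lncenc1, known from pluripotent cells, fell by 5.20 ± 0.50 (adjusted p = 0.0135). These 4 probe sets were all that passed the threshold, 3 on chip A and 1 on chip B, and each was separate from the fertilized samples in all 3 gynogenetic samples. A further probe set of Plagl1 on each chip did not move with it, at 0.09 on chip A and 1.34 on chip B. The called probe set of Plagl1 may also bind related sequences by the suffix of its name.

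Among 18 measured paternally expressed imprinted genes, 1 fell in gynogenetic embryos (Plagl1), and the other 17 did not pass, whether adjusted over all genes or adjusted over the list alone. Values of members that did not pass were −3.31 ± 1.14 for Peg3, a zinc finger gene read from the paternal allele, −2.89 ± 0.87 for Mcts2, a retrogene, and −1.34 ± 0.59 for Mest, an imprinted hydrolase-like gene (−0.83 without fertilized replicate 3). The list test gave an adjusted p of 0.0138 towards lower values over the 14 members on chip A, with a median of −0.05 and a mean of −0.84 on the log2 scale (adjusted p = 0.183 with an estimated correlation). It was 0.0721 without gynogenetic replicate 3 and 0.0535 and 0.0911 without fertilized replicates 1 and 3. Maternally expressed imprinted genes had 27 measured members, none of which passed, whether adjusted over all genes or adjusted over the list alone. Meg3, a maternally expressed noncoding RNA, was at 1.34 ± 0.39 and Osbpl5, an oxysterol-binding protein, at 1.51 ± 0.54, and the list test gave an adjusted p of 0.146 (median 0.35). Without fertilized replicate 3 Osbpl5 was at 0.99 and the list test gave 0.00934. The list of genes with paternal expression under maternal H3K27me3, a histone mark that can silence maternal alleles without DNA methylation, had 24 measured members. Its members Slc38a4 and Sfmbt2 fell, 3 members fell when adjusted over the list alone (with Gab1, an adaptor of growth factor receptors, at −2.57 ± 0.54), and the other members did not pass. Of its 19 members on chip A, 15 had lower and 4 higher values, with a median of −0.43 and an adjusted p of 6.49e-07 (adjusted p = 0.0208 with an estimated correlation). Over 11 genes of chip B the list did not pass, with a median of −0.34 (adjusted p = 0.454, adjusted p = 0.503 with an estimated correlation). Of these, the 5 not tested on chip A had 3 higher and 2 lower values, with a median of 0.06. The members of this list came from general knowledge, and some of them may first have been found imprinted in embryos of these kinds or in these samples. Their direction is therefore not wholly independent evidence in any of the comparisons.

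X-linked genes lay higher in gynogenetic than in fertilized embryos. Of 307 genes of the X chromosome on chip A, 243 had higher and 64 lower values, with a median of 0.49 on the log2 scale against 0.01 to 0.10 for the medians of the 19 autosomes. The list test gave an adjusted p of 1.73e-10 (adjusted p = 0.0208 with an estimated correlation), while no single X-linked gene passed, also when adjusted over the list alone. Examples of values that did not pass were 0.94 ± 0.18 for Bex3, 2.39 ± 0.47 for Bex2, 2.35 ± 0.54 for Morc4, a CW-type zinc finger ATPase, and 2.48 ± 0.60 for F8, coagulation factor VIII. The X-linked median on chip B was 0.18 (adjusted p = 0.015, and adjusted p = 0.0423 with an estimated correlation), and also 0.18 over the 186 genes not tested on chip A (autosomes −0.07 to 0.15). Cholesterol synthesis genes also moved as a list, with 14 of 16 members on chip A at higher values (median 0.71, adjusted p = 5.12e-05, adjusted p = 0.217 with an estimated correlation). No member passed alone, and Cyp51 (2.39 ± 0.69) and Sqle (1.37 ± 0.45), sterol synthesis enzymes, and Mvd (1.38 ± 0.57), of the mevalonate pathway, had the largest statistics. Fertilized replicate 3 lay below the other fertilized samples in this list (median −0.67). Without it the list test gave 0.000189 and Sqle was at 0.83.

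Oocyte genes were lower in gynogenetic than in fertilized embryos as a list (14 of 15 members on chip A, median −1.48, adjusted p = 5.12e-05, adjusted p = 0.466 with an estimated correlation), with an adjusted p of 0.873 without fertilized replicate 3. Nlrp14 (−3.27 ± 1.31) and Gdf9 (−2.83 ± 1.65), at −1.44 and −0.55 without that sample, were among the members, none of which passed. The list of imprint maintenance and chromatin genes gave an adjusted p of 0.0138 towards lower values (12 of 17 members, median −0.30, adjusted p = 0.27 with an estimated correlation). Without gynogenetic replicate 1 it gave 0.055, and without fertilized replicate 3 it gave 0.0947. Zfp57, a zinc finger protein that protects imprints and is stored in the oocyte, had a mean signal of 3540 ± 5580 (SD, n = 3) in fertilized embryos. Its log2 difference of −4.76 ± 1.77 did not pass, nor did that of Uhrf1 (−1.52 ± 0.53), a partner of the maintenance methyltransferase Dnmt1 (−1.10 ± 0.45). Without fertilized replicate 3 Zfp57 was at −2.60 and Dnmt1 at −0.59. Among probe sets with a gene name the largest moderated statistics towards higher values did not pass, those of Bex3, Foxa2 (2.04 ± 0.36), a transcription factor of the endoderm, Grasp (3.06 ± 0.49), and on chip B Syndig1 (2.23 ± 0.37), Ldoc1 (2.66 ± 0.44) and Runx1t1 (2.07 ± 0.38). Towards lower values on chip B the next such statistics after Lncenc1, those of Gna13 (−2.40 ± 0.37), a G protein subunit, and 5830454E08Rik (−2.50 ± 0.42), did not pass either.

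With limma and Benjamini-Hochberg adjustment, 617 of 16969 probe sets on chip A had an unadjusted p under 0.05 where 848.5 are expected by chance, and 991 of 16883 did so on chip B (844.2 expected). The groups did not overlap in 9.17% of probe sets on chip A and 12% on chip B, where chance gives 10%. The count of 3 on chip A became 1 without androgenetic replicate 1, 0 without gynogenetic replicate 2, fertilized replicate 1 or fertilized replicate 2, and 6 without fertilized replicate 3. The count of 1 on chip B became 0 without androgenetic replicate 1, gynogenetic replicate 1 or 2, or any of the fertilized samples, and 2 without gynogenetic replicate 3. The adjusted p of Slc38a4 was then 0.0516 without gynogenetic replicate 2 and 0.0752 and 0.0625 without fertilized replicates 1 and 2. The highest values for the other called genes were 0.161 for Sfmbt2 without fertilized replicate 1, 0.258 for Plagl1 without gynogenetic replicate 1 and 0.149 for Lncenc1 without gynogenetic replicate 2. The arrays were washed on 2 fluidics stations. With the station as a block the counts were 2 and 0, the X-linked list gave 5.85e-10, the H3K27me3 list gave 3.9e-06 and the paternally expressed list gave 0.0198 on chip A. Slc38a4 and Sfmbt2 also passed with this block, while Plagl1 gave 0.0507 and Lncenc1 0.0679. Within station 2 (2 gynogenetic and 2 fertilized samples) the X-linked median was 0.43 (adjusted p = 9.57e-13) and that of the H3K27me3 list −0.48 (adjusted p = 8.24e-06), with no probe set past the threshold by limma and 964 at an unadjusted p under 0.05. Station 1 held 1 gynogenetic sample and fertilized replicate 3, too few for a test of the kinds, and these medians were 0.47 and −0.15 there. All 3 genes called on chip A kept their direction within each station. Lncenc1 kept its direction within station 2, the only one that held both kinds on chip B. The groups did not overlap for these genes, so their direction was bound to hold and is no check of the station. The X-linked median within station 2 on chip B was 0.29 (adjusted p = 0.00609).

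Androgenetic embryos were compared with fertilized embryos to find transcripts that depend on a maternal genome. On chip B, Ttl, the tubulin tyrosine ligase, rose by 3.67 ± 0.42 on the log2 scale (SE, n = 3 and 3; limma adjusted p = 0.0291). Ccdc138, a coiled-coil protein gene, fell by 4.31 ± 0.42 (adjusted p = 0.0169), Xkrx, an X-linked gene of the Kell blood group complex family, fell by 3.66 ± 0.43 (adjusted p = 0.0291), and Gle1, a factor of mRNA export, fell by 3.29 ± 0.42 (adjusted p = 0.0481). On chip A no probe set passed with limma, although 957 of 16969 had an unadjusted p under 0.05 (848.5 expected by chance) and the smallest adjusted p was 0.0722. Among probe sets with a gene name the largest moderated statistic towards lower values there belonged to Tktl1, an X-linked transketolase-like gene (−4.32 ± 0.52, adjusted p = 0.098, or 0.0285 without fertilized replicate 3). It was followed by Pgk1, the X-linked phosphoglycerate kinase (−2.72 ± 0.37), and Aldh18a1, an enzyme of proline synthesis (−2.96 ± 0.45). Towards higher values the largest statistics among them, none of which passed, belonged to Derl3, of endoplasmic reticulum degradation (2.84 ± 0.43), Cux1, a homeobox gene (1.90 ± 0.35), and Hspb1, a small heat shock protein (1.64 ± 0.32), and on chip B, after Ttl, to Cfap126 (2.61 ± 0.49) and Bnip2 (2.09 ± 0.40). Other probe sets of Ttl on chip A were at 0.10, 0.16 and 0.41, and the further probe sets of Gle1 lay between −1.04 and 0.13.

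No member of either imprinted list passed in androgenetic against fertilized embryos. In the maternally expressed list Cobl, an actin nucleator, was at −4.60 ± 0.76 (adjusted p = 0.257), with a mean signal of 540 ± 746 (SD, n = 3) in fertilized embryos. It was the 1 member of 27 that passed when adjusted over the list alone. Ppp1r9a, a neural actin-binding protein of the same list, was at −1.98 ± 1.12. In the paternally expressed list Mcts2 was at 2.16 ± 0.87 (1.10 without fertilized replicate 3) and Inpp5f, a phosphoinositide phosphatase, at −1.28 ± 0.47. The tests of the maternally and paternally expressed lists gave adjusted p of 0.675 (median −0.08) and 0.912, and the latter pointed to lower values with a mean of −0.04 while its median was 0.08. The H3K27me3 list had 17 of 19 members on chip A at higher values, with a median of 0.42 and an adjusted p of 0.0491 (adjusted p = 0.301 with an estimated correlation). That value was 0.205 and 0.0795 without androgenetic replicates 1 and 3, 0.0534 and 0.0602 without gynogenetic replicates 2 and 3, and 0.113 and 0.126 without fertilized replicates 2 and 3. Bbx (1.75 ± 0.71), Slc38a4 (1.10 ± 0.54), Epas1, a hypoxia-inducible factor (0.85 ± 0.53), and Mbnl2, a splicing factor (2.25 ± 1.13), were members that did not pass. Without fertilized replicate 3 Bbx was at 1.26, Slc38a4 at 0.50, Epas1 at 0.18 and Mbnl2 at 0.61.

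Targets of p53 and apoptosis genes had higher values in androgenetic embryos in 19 of 22 members on chip A (median 0.49, adjusted p = 0.00063, adjusted p = 0.301 with an estimated correlation). Their members did not pass alone, as for Zmat3, an RNA-binding target of p53 (1.51 ± 0.47), Phlda3 (1.77 ± 0.97), Bcl2l11, a proapoptotic BH3 protein (1.18 ± 0.59), and Perp, a membrane protein of desmosomes (0.37 ± 0.18). Fertilized replicate 3 lay below the other fertilized samples in this list (median −0.56). Without it the list test gave 0.00109, and Phlda3 was at 0.36, Bcl2l11 at 0.59 and Perp at 0.175. X-linked genes had a median of −0.21 with 188 lower and 119 higher values on chip A, below the 19 autosomes, whose medians ran from −0.03 to 0.11 (adjusted p = 0.00116, adjusted p = 0.301 with an estimated correlation). The X-linked median on chip B was −0.12 (adjusted p = 0.0533). With arrays scaled to a common trimmed mean it was 0.05, below the autosomes at 0.08 to 0.20. Xkrx was the 1 X-linked gene that fell, while 3 fell when adjusted over the list alone. Clcn5, an endosomal chloride transporter, was at −1.55 ± 0.29 and Tceal9 at −0.73 ± 0.14 without passing. Oocyte genes were lower as a list (14 of 15 members on chip A, median −1.52, adjusted p = 0.00063, adjusted p = 0.59 with an estimated correlation), with an adjusted p of 0.552 without fertilized replicate 3. Gja4, a connexin of the oocyte (−4.17 ± 1.14), Zp2, of the zona pellucida (−1.73 ± 0.88), and Tle6 (−2.09 ± 1.08) did not pass, and were at −2.53, −0.65 and −0.70 without that sample. Imprint maintenance and chromatin genes had lower values in 14 of 17 members (median −0.49, adjusted p = 0.0129, adjusted p = 0.301 with an estimated correlation), and the test gave 0.122 without fertilized replicate 3 and 0.385 without androgenetic replicate 2. Uhrf1 (−1.54 ± 0.53), Zfp57 (−4.48 ± 1.77, or −2.32 without fertilized replicate 3), Trim28, a corepressor that binds with Zfp57 (−0.51 ± 0.21), and Dnmt3b (−0.49 ± 0.23) did not pass.

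The count of 0 on chip A became 3 without fertilized replicate 3. The count of 4 on chip B (1 higher, 3 lower, and 1140 at an unadjusted p under 0.05 of 844.2 expected) became 7 without gynogenetic replicate 3, 1 without fertilized replicate 1, and 0 without any 1 of the other 7 samples. The groups did not overlap in 10.3% of probe sets on chip A and 12.3% on chip B, where chance gives 10%. With the station as a block no probe set passed by limma on either chip, the X-linked list gave 0.185, the H3K27me3 list 0.107, the p53 list 0.00751 and the oocyte list 1.27e-07. On chip A this fit leans more on fertilized replicate 3. Gja4 was at −5.76 and Zp2 at −2.82 with the block, against −2.53 and −0.65 without that sample. These list values are therefore no check of the station that is free of fertilized replicate 3. Station 1 held all 3 androgenetic samples and, on chip A, fertilized replicate 3 as the only fertilized sample. That comparison sets a single sample against the spread of the androgenetic samples alone, so its 328 calls are no test of the kind of embryo. The X-linked median in it was −0.02 against 0.02 to 0.30 for the autosomes, the H3K27me3 median was 0.60 and the p53 median was 0.84. On chip B no station held both kinds, so station and kind of embryo can be set apart there only through the gynogenetic samples. Ttl, Ccdc138, Xkrx and Gle1 were therefore compared with fertilized embryos across stations only.

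Androgenetic and gynogenetic embryos, which differ in the parental origin of the whole genome, were compared directly. Slc38a4 was higher in androgenetic embryos by 7.77 ± 0.54 on the log2 scale (SE, n = 3 and 3; limma adjusted p = 0.00173), with mean signals of 4080 ± 483 and 6.43 ± 4.62 (SD, n = 3). The lower signal lies under the pseudocount of 11, and the change ran from 5.85 to 9.20 over other scalings, pseudocounts and blocks. Sfmbt2 was higher by 5.83 ± 0.51 (adjusted p = 0.00437), Plagl1 by 5.16 ± 0.60 (adjusted p = 0.0168) and, on chip B, Lncenc1 by 6.52 ± 0.50 (adjusted p = 0.000771). In the opposite direction Tktl1 was at −5.46 ± 0.52 (adjusted p = 0.0065), Pgk1 at −3.83 ± 0.39 (adjusted p = 0.00884), Ccdc138 at −5.63 ± 0.42 (adjusted p = 0.000771) and Xkrx at −4.42 ± 0.43 (adjusted p = 0.00451). In all, 24 probe sets differed on chip A (11 higher and 13 lower in androgenetic embryos) and 9 on chip B (5 higher and 4 lower). Without further scaling of the signals the counts were 12 (7 higher and 5 lower) and 8 (5 higher and 3 lower), with median centring they were 20 (12 higher and 8 lower) and 7 (4 higher and 3 lower), and with a common trimmed mean 25 (9 higher and 16 lower) and 7 (4 higher and 3 lower).

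**Figure D2:**
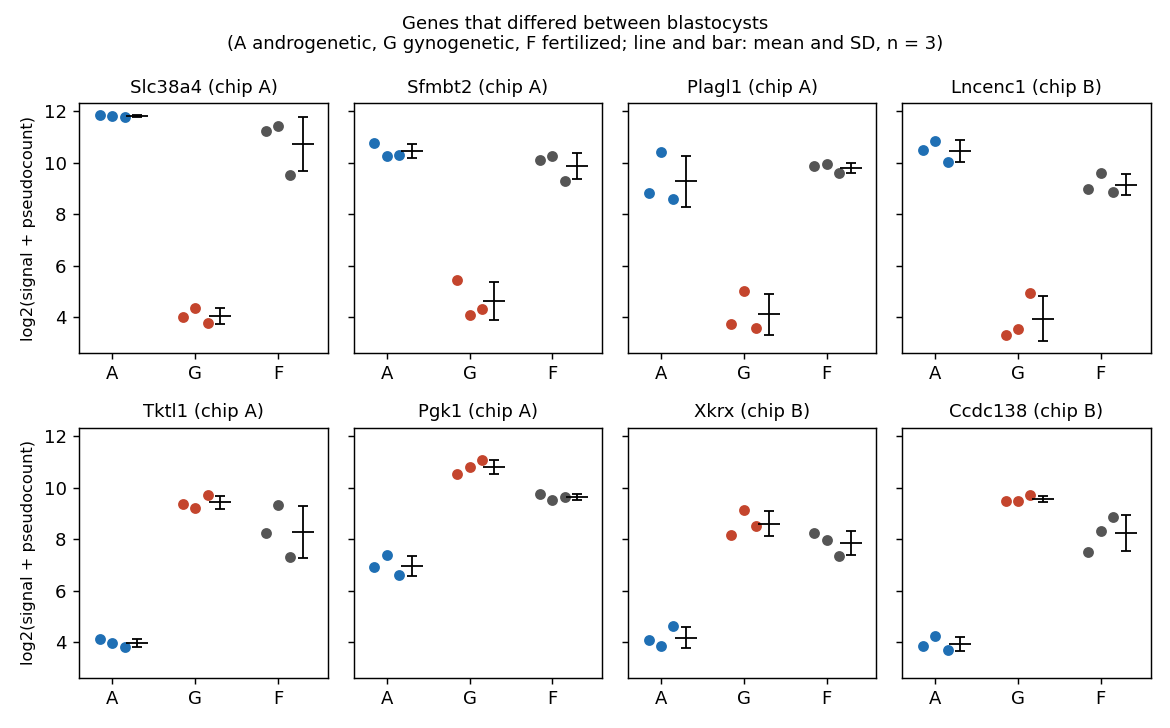
Quantile-normalized log2(signal + pseudocount) of 8 genes in androgenetic (A), gynogenetic (G) and fertilized (F) blastocysts, with 1 dot per sample and a line and bar for the mean and SD (n = 3). Slc38a4, Sfmbt2, Plagl1 and Lncenc1 are lowest in the gynogenetic samples, and Tktl1, Pgk1, Xkrx and Ccdc138 are lowest in the androgenetic samples.

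Other autosomal genes that were higher in androgenetic embryos were Anxa8, an annexin (4.43 ± 0.61, adjusted p = 0.0349), Gab1 (4 ± 0.56, adjusted p = 0.035), Med1, a subunit of the Mediator complex (3.82 ± 0.52, adjusted p = 0.0327), and Jade1, a subunit of a histone acetyltransferase complex (3.65 ± 0.52, adjusted p = 0.035). Mfsd1, a lysosomal transporter, was higher by 2.64 ± 0.36 (adjusted p = 0.0349). Over other scalings, pseudocounts and blocks the change ran from 1.27 to 3.79 for Mfsd1, from 2.15 to 5.99 for Gab1 and from 2.14 to 4.90 for Jade1. Also higher in androgenetic embryos, on chip B, were 5830454E08Rik, a transcript without a named function (3.77 ± 0.42, adjusted p = 0.0108), Ttl (3.62, adjusted p = 0.0129) and Cox7b2, a subunit of cytochrome oxidase (3.60, adjusted p = 0.0445). Autosomal genes that were lower were Cxcl14, a chemokine (−4.53 ± 0.56, adjusted p = 0.0181), Prom1, a membrane glycoprotein (−3.78 ± 0.53, adjusted p = 0.035), Tpm2, a tropomyosin (−2.81 ± 0.40, adjusted p = 0.035), and on chip B Gle1 (−3.11, adjusted p = 0.0404). Probe sets of the same gene did not always move together. A second probe set of Jade1 also passed (3.34, adjusted p = 0.0168) and its others were at 2.45 and 2.53, while second probe sets of Gab1 and Tpm2 were at 3.11 (adjusted p = 0.0812) and −2.95 (adjusted p = 0.0513). A further probe set of Gab1 was at 0.96 and 2 of Tpm2 were at −0.43 and −0.61, without passing. Further probe sets of Med1, between −1.02 and 0.71, of Mfsd1, at 0.07 and 0.12, of Ttl, between 0.15 and 0.58, of Gle1, between −0.29 and 1.15, of Cxcl14, at −0.37, and of Plagl1, at 0.58 on chip A and −0.82 on chip B, did not differ. Of the 24 probe sets on chip A, 3 have no single gene name.

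Among the 18 measured paternally expressed imprinted genes 1 was higher in androgenetic embryos (Plagl1), and none of the 27 maternally expressed genes passed. When adjusted over the list alone, 2 paternally expressed genes were higher (with Mcts2, at 5.05 ± 0.87), 1 was lower (Inpp5f, at −1.82 ± 0.47), and 1 maternally expressed gene was lower (Cobl, at −4.55 ± 0.76, adjusted p over all genes 0.0916, or 0.005 without fertilized replicate 3). Meg3 was at −1.42 ± 0.39 without passing. The list tests gave adjusted p of 0.0425 for paternally expressed genes (10 of 14 members on chip A higher, median 0.24, mean 0.80) and 0.0394 for maternally expressed genes (18 of 21 lower, median −0.32), with adjusted p = 0.175 for each with an estimated correlation. Each rested on single samples. For paternally expressed genes the adjusted p was 0.451 and 0.062 without androgenetic replicates 1 and 2, 0.0834 and 0.137 without gynogenetic replicates 1 and 3, and 0.0512 and 0.0656 without fertilized replicates 1 and 3. For maternally expressed genes it was 0.155 and 0.0804 without androgenetic replicates 2 and 3, and 0.111 and 0.0507 without gynogenetic replicates 1 and 2. The H3K27me3 list had 17 of 19 members on chip A higher in androgenetic embryos (median 0.91, adjusted p = 9.95e-10, adjusted p = 0.00822 with an estimated correlation). This direction is not wholly independent evidence, since some members may first have been found imprinted in such embryos or in these samples. By the probe set that stood for each gene, 2 of 24 members passed (Slc38a4 and Sfmbt2), and the members Gab1 and Jade1 passed by another probe set. Of the 24 members, 6 were higher when adjusted over the list alone, with Gab1 (3.11 ± 0.54), Mbnl2 (5.40 ± 1.13), Bbx (2.81 ± 0.71) and Epas1 (1.83 ± 0.53). Over 11 genes of chip B the list's median was 0.85 (adjusted p = 0.00338, adjusted p = 0.063 with an estimated correlation), but the 5 of them not tested on chip A had 3 higher and 2 lower values, with a median of 0.34.

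X-linked genes were lower in androgenetic embryos, with 239 of 307 genes lower on chip A and a median of −0.62, against −0.08 to 0.05 for the medians of the 19 autosomes (adjusted p = 2.9e-18, adjusted p = 0.00619 with an estimated correlation). Of the X-linked genes 8 were called lower and none higher by the probe set that stood for each gene, and 56 were lower and 2 higher when adjusted over the list alone. Besides Tktl1, Xkrx and Pgk1, the genes included Morc4 (−4.16 ± 0.54), Sh3bgrl (−2.81 ± 0.41, while the probe set that stood for it was at −1.78 without passing), Pja1, a ubiquitin ligase (−2.39 ± 0.29), Clcn5 (−2.16 ± 0.29), Tceal9 (−1.22 ± 0.14) and on chip B Ldoc1 (−4.13 ± 0.44). All 3 tested probe sets of Pgk1 were lower, 2 of which may also bind related sequences by the suffix of their names. The called probe sets of Sh3bgrl and of Plagl1 carry the same suffix. The change of Sh3bgrl ran from −2.86 to −1.17 over other scalings, pseudocounts and blocks. Mid1, an X-linked microtubule-associated ubiquitin ligase, had 1 probe set on chip B that was higher by 4.79 ± 0.47 (adjusted p = 0.00451), while its probe set on chip A was at 0.03. The X-linked median was −0.24 on chip B (adjusted p = 6.62e-07, adjusted p = 0.00272 with an estimated correlation), and −0.21 over the 186 genes not tested on chip A (autosomes −0.02 to 0.13).

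**Figure D3:**
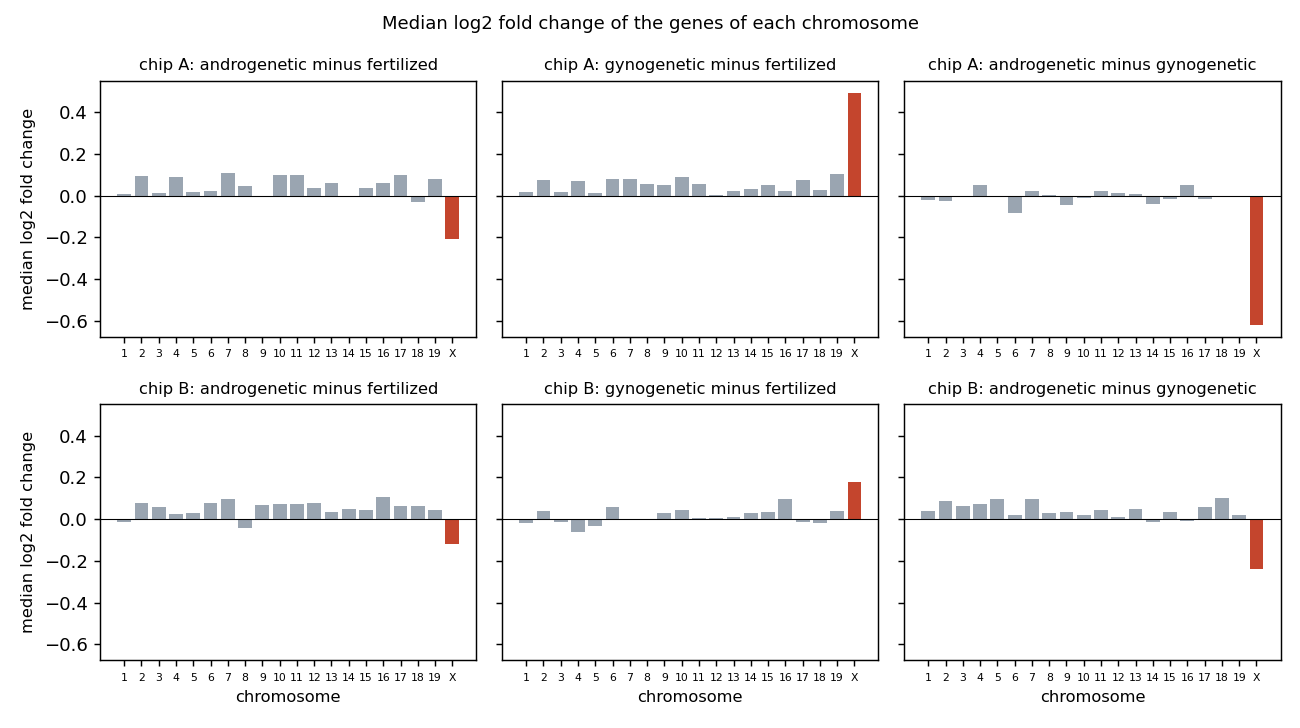
Bars from 0 show the median log2 fold change of the genes of each chromosome in the 3 comparisons on chip A (top) and chip B (bottom), with the X chromosome in red. The X bar lies outside the range of the autosomes in all 6 panels, at −0.62 on chip A and −0.24 on chip B in androgenetic against gynogenetic embryos.

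Trophectoderm genes were lower in androgenetic embryos as a list (18 of 23 members, median −0.26, adjusted p = 0.0035, adjusted p = 0.175 with an estimated correlation). Members did not pass alone, as for Eomes (−2.29 ± 0.60) and Elf5 (−1.49 ± 0.51), transcription factors of trophoblast stem cells, and the keratin Krt7 (−1.69 ± 0.61). Targets of p53 and apoptosis genes were higher as a list (19 of 22 members, median 0.46, adjusted p = 0.00206, adjusted p = 0.175 with an estimated correlation), with Bcl2l11 at 1.73 ± 0.59, Bak1, a proapoptotic protein of mitochondria, at 1.03 ± 0.48 and Bbc3, a BH3 protein, at 1.33 ± 0.65. Cholesterol synthesis genes were lower (13 of 16 members, median −0.43, adjusted p = 0.0175, adjusted p = 0.385 with an estimated correlation), as were genes of oxidative phosphorylation (24 of 34 members, median −0.12, adjusted p = 0.0394, adjusted p = 0.385 with an estimated correlation). The X-linked members Nsdhl, of sterol synthesis (−1.42 ± 0.47), and Ndufa1, of respiratory complex I (−1.41 ± 0.46), had the largest statistics in these lists without passing. For cholesterol synthesis the adjusted p was 0.0699 and 0.233 without androgenetic replicates 2 and 3, and 0.18, 0.0507 and 0.0792 without gynogenetic replicates 1, 2 and 3. For oxidative phosphorylation it was 0.0612 and 0.478 without androgenetic replicates 1 and 2, 0.229 and 0.0766 without gynogenetic replicates 2 and 3, and 0.708 without scaling of the signals.

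Lists that passed in no comparison gave these adjusted p in androgenetic against gynogenetic embryos. The value was 0.611 for the inner cell mass and epiblast list, 0.193 for primitive endoderm, 0.719 for trophoblast differentiation, 0.982 for cumulus, somatic and blood cells, 0.919 for Y-linked genes, 0.611 for glycolysis, 0.919 for ribosomal proteins and 0.767 for the cell cycle. It was 0.919 for the unfolded protein and amino acid response, 0.533 for heat shock and oxidative stress, 0.349 for junctions and cavitation, and 0.347 for feedback genes of the FGF and MAPK pathway. The smallest value among these lists was 0.289 in androgenetic and 0.146 in gynogenetic against fertilized embryos. Oocyte genes, at 0.925, and imprint maintenance genes, at 0.919, did not differ detectably between the uniparental kinds. The list of genes activated at the stage of the first cleavage had 2 measured members, with a median of −0.05, and the list of X inactivation RNAs had 1 on chip A (Xist, −0.29 ± 0.78) and 1 on chip B (0.16), too few for the test. None of the 3 Xist probe sets passed in any comparison, with mean signals of at most 91.6. Eif2s3y, a Y-linked translation factor, was at 1.82 ± 0.92 in androgenetic against gynogenetic embryos without passing.

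The number of calls in androgenetic against gynogenetic embryos depended on single samples and on whether the station was fitted as a block. On chip A the count of 24 became 7 and 12 without androgenetic replicates 1 and 3, 2, 8 and 6 without gynogenetic replicates 1, 2 and 3, and 75 without fertilized replicate 3, which enters through the spread and the normalization. On chip B the count of 9 became 4 without androgenetic replicate 2, 5 without gynogenetic replicate 2 and 47 without fertilized replicate 3. Slc38a4, Sfmbt2, Lncenc1, Mid1, Ccdc138 and Xkrx passed with any 1 sample left out, and Tktl1 gave 0.0641 without gynogenetic replicate 1. The other called genes gave values of up to 0.243 (Cox7b2, without gynogenetic replicate 2). Their direction was kept, which says little for genes chosen because they passed. With the station as a block the counts were 5 and 1. All androgenetic samples were on station 1, so this block also costs precision, and fewer calls need not mean smaller differences. With it Slc38a4 went from 7.77 to 8.40, Sfmbt2 from 5.83 to 5.71, Tktl1 from −5.46 to −4.93 and Anxa8 from 4.43 to 5.23. The adjusted p was then 1.73e-10 for the X-linked list, 5.1e-08 for the H3K27me3 list, 0.0156 for the maternally expressed list and 0.00122 for the p53 list. The paternally expressed list gave 0.327, the trophectoderm list 0.239, the cholesterol list 0.314 and the list of oxidative phosphorylation 0.379. Station 1 held 3 androgenetic samples and only gynogenetic replicate 1, too few for a test of the kinds of embryo, and station 2 held no androgenetic sample. The X-linked median within station 1 was −0.54 on chip A and −0.21 on chip B, and the H3K27me3 median was 1.04 and 0.83. The 18 called probe sets on chip A (2 of them of Pgk1) and 6 on chip B that the rule for named genes took kept their direction there. Their groups did not overlap, so this direction was bound to hold and is no check of the station. Clcn5, Cox7b2, Ttl and Gle1 were not compared within the station. At an unadjusted p under 0.05 there were 1123 probe sets on chip A (848.5 expected by chance) and 1208 on chip B (844.2 expected), and the groups did not overlap in 13.6% and 12.8% of probe sets, where chance gives 10%.

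A moderated F test over the 3 kinds of embryo called 7 probe sets on chip A, which belong to Slc38a4, Sfmbt2, Plagl1, Tktl1, Pgk1 (2 probe sets) and 1 unnamed transcript, and 8 on chip B, which belong to Lncenc1, Ccdc138, Xkrx, Mid1, Ttl, Ldoc1, 5830454E08Rik and Gle1. These names were taken after the values were seen. On chip A the count became 1 without androgenetic replicate 1 or 3, gynogenetic replicate 2 or fertilized replicate 1, 2 without gynogenetic replicate 1 or 3, 4 without fertilized replicate 2 and 31 without fertilized replicate 3. On chip B it became 2 without androgenetic replicate 2 or fertilized replicate 2, 3 without androgenetic replicate 3, 5 without gynogenetic replicate 1 or fertilized replicate 1, 4 without gynogenetic replicate 2 and 23 without fertilized replicate 3. With the station as a block it was 1 on each chip. The effects of the uniparental kinds against the same fertilized arrays had a Pearson correlation of 0.463 across probe sets on chip A and 0.46 on chip B, where genes are not independent replicates. Without fertilized replicate 3 it was 0.263 on chip A and 0.459 on chip B. Simulated unchanged groups gave 0.5 on each chip against 3 fertilized arrays (0.483 to 0.517 and 0.486 to 0.519 in 100 simulations) and 0.6 against 2 (0.582 to 0.617 and 0.577 to 0.614). The covariance was 0.222 against a simulated 0.194 on chip A and 0.215 against 0.166 on chip B, and 66.5% and 67.8% of probe sets had the same sign in both comparisons, against a simulated 66.7% on each chip. No probe set was called in both comparisons with fertilized embryos, with 0 expected for independent lists on chip A and 0.000178 on chip B. With 3 fertilized samples the controls could not be split into 2 sets of at least 2. The simulation held the shared controls but gave all arrays the same spread, although fertilized replicate 3 stood apart. Without fertilized replicates 1 and 2 the correlation was 0.673 and 0.67 on chip A and 0.6 and 0.618 on chip B. The excess covariance can therefore not be read as a response common to the uniparental kinds.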

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

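Of the tests in this part, the oocyte list in fertilized replicate 3, the X-linked list on chip B and the X-linked median with the station as a block were chosen only after the results were seen.

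Fertilized replicate 3 stood out by 1 ratio of control probe sets that no comparison uses. Its actin ratio of 3′ to middle signal was 10.8 on chip A and 11.7 on chip B, where the highest other values were 2.99 and 3.13. The Gapdh controls did not set it apart, with ratios of 3′ to middle signal of 2.51 and 2.88 against 2.48 and 2.68 in androgenetic replicate 3. Their ratios of 3′ to 5′ signal were 17.2 and 18.4 in fertilized replicate 3, against 166 and 100 in gynogenetic replicate 3. By the actin ratio of 3′ to 5′ signal fertilized replicate 3 did not stand alone, at 93.8 and 110 against 95.5 and 108 in gynogenetic replicate 3. The oocyte list of fertilized replicate 3 lay 4.17 above the other fertilized samples (median log2 difference, 14 of 15 members higher), with Gdf9 at 8660, Tle6 at 5740 and Nlrp5 at 5320. The next list upwards, imprint maintenance, lay at 0.275. The lists furthest below were cholesterol synthesis at −0.674, inner cell mass and epiblast at −0.644, p53 targets at −0.564 and primitive endoderm at −0.448. Of 10000 random lists of matched signal, 100% had a lower median (−1.34 to 1.87). These lists were matched on mean signal only, and the oocyte list was chosen after it was seen to stand out. They therefore cannot decide on shortened cDNA or the later hybridization run as the whole cause of the oocyte signal. Oocytes alone under a wrong label are argued against by the trophectoderm list, which lay at only −0.314. RNA of oocytes or of embryos arrested early may have been in that sample, which stays a hypothesis. Of the 15 genes 1 (Dppa3) is in another list, and per the labels no contaminating cells were seen by eye. In fertilized replicates 1 and 2, 8 of the 15 genes lay above the chip's median as well. That says little, since the median signals of these arrays were only 44.73 and 65.67, and Nlrp5 was at 90 and 117 there. A biological difference between fertilized embryos was not tested.

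The X-linked list drew attention because the uniparental kinds moved apart from fertilized embryos in opposite directions, and the direct comparison that tests this difference gave a median of −0.62 on chip A. The fluidics station as the whole cause cannot be excluded, since all androgenetic samples were on station 1. With the station as a block the list had an adjusted p of 1.73e-10 and a median of −0.505, below every autosome (−0.0414 to 0.151). That fit estimates the station effect only through gynogenetic replicate 1 and fertilized replicate 3, and the latter stood apart, so it cannot decide. The value within station 1, −0.542, rests on 1 gynogenetic sample and excludes nothing. Within station 2, 2 gynogenetic against 2 fertilized samples had an X-linked median of 0.43 on chip A (autosomes −0.0729 to 0.0475). That part of the shift did not need a difference of station. A bias of signal level is argued against by 10000 random lists of matched signal, of which 0% had a lower median (−0.135 to 0.0998). Chip B, in the same samples, gave a median of −0.237 (autosomes −0.0136 to 0.102), or −0.212 (autosomes −0.0239 to 0.126) over the 186 X-linked genes not tested on chip A, which does not tell the explanations apart. Gynogenetic embryos hold no paternal genome and so no Y chromosome, while the other kinds can hold one. The number of X chromosomes can therefore differ between the kinds by design. Its effect cannot be told apart here from that of the parental origin of the X chromosomes. The strain of the parents also stays open, and none of these hypotheses was tested.

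The list of paternal expression under maternal H3K27me3 was singled out in the same way, with a median of 0.906 in androgenetic against gynogenetic embryos (17 of 19 members higher, adjusted p = 9.95e-10), and no explanation was weighed. Some members may first have been found imprinted in such embryos or in these samples, so the direction may be built into the list.

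Other splits of the samples were counted for the comparisons. In the moderated F test over the 3 kinds, 1 of 100 splits (drawn from 280) gave as many probe sets as the real one on chip A (7, highest other 0) and 1 of 100 on chip B (8, highest other 6). That 1 was the real split itself, which argues against a chance split of the samples as the source of these counts. All androgenetic samples were on station 1, so the splits do not set the kind of embryo apart from the station. With the station as a block the F test called 1 probe set on each chip. For 3 samples against 3 there are 10 splits, too few for a share under 0.05, and the following values are given only with that limit. In androgenetic against fertilized embryos 10 of the 10 splits reached the real count on chip A (0, highest other 0) and 1 on chip B (4, highest other 0). In gynogenetic against fertilized embryos 1 split did on chip A (3, highest other 0) and 1 on chip B (1, highest other 0), and in androgenetic against gynogenetic embryos 1 did on chip A (24, highest other 1) and 1 on chip B (9, highest other 1).

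For gene lists the size of a result is the negative log10 of the camera p, and the real split is counted. In androgenetic against fertilized embryos 1 split was as large for the H3K27me3 list (1.95, highest other 1.61), 5 for oocyte genes (4.29, highest other 5.4), 1 for p53 targets (4.24, highest other 2.82), 1 for imprint maintenance (2.63, highest other 2.53) and 1 for X-linked genes (3.8, highest other 1.93). In gynogenetic against fertilized embryos 1 split was as large for paternally expressed genes (2.42, highest other 1.44), 1 for the H3K27me3 list (7.23, highest other 1.79), 4 for oocyte genes (5.03, highest other 6.2), 1 for cholesterol synthesis (5.04, highest other 1.9), 1 for imprint maintenance (2.48, highest other 2.22) and 1 for X-linked genes (11.1, highest other 3.32). In androgenetic against gynogenetic embryos 1 split was as large for paternally expressed genes (1.81, highest other 1.55), 1 for maternally expressed genes (1.9, highest other 1.18), 1 for the H3K27me3 list (10, highest other 2.07), 1 for trophectoderm (3.2, highest other 1.87), 3 for oxidative phosphorylation (1.93, highest other 3.32), 1 for p53 targets (3.55, highest other 1.76), 2 for cholesterol synthesis (2.4, highest other 2.46) and 1 for X-linked genes (18.9, highest other 5.08).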

How the results depend on the processing

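The unscaled signals, the common trimmed mean and the list tests on chip B were chosen after seeing the data. Of 125 results for named genes, 32 passed the threshold. All 32 kept their direction with any sample left out and in the settings run for single genes. These were the unscaled signals, median centring, 2 pseudocounts, the replicate block and the station block, of which the filter left 5 of 6 for Sh3bgrl. The kept direction says little, since these results passed with groups that did not overlap, so leaving out 1 sample can hardly reverse it. Of these 32, 18 also passed without scaling, 27 without fertilized replicate 3, 12 with the replicate number as a block and 5 with the station as a block. With any 1 sample left out 6 passed each time, namely Slc38a4, Sfmbt2, Lncenc1, Mid1, Ccdc138 and Xkrx in androgenetic against gynogenetic embryos. Signals near background limit the ratios, since the log2 change of a gene that is almost silent in 1 group depends on the pseudocount, and small changes are limited by the number of arrays (a change of 1 was recovered in 6% of simulated cases on chip A). Where no reason is given below, the cause was not tested.

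Samples share only a replicate number, since the labels state no pairing or shared block and the correlations of deviations between samples of the same number, −0.355 to 0.218 on chip A and −0.178 to 0.0848 on chip B, were not all above 0.1. As a hint from the data, the gynogenetic and fertilized samples of the same number correlated at 0.218, 0.141 and 0.0817 on chip A and 0.0848, 0.0732 and 0.0692 on chip B, higher than any gynogenetic and fertilized samples of different numbers (up to 0.0644 and 0.0406). With the replicate number as a block, which costs degrees of freedom, chip A had 0 calls in androgenetic and 3 in gynogenetic against fertilized embryos, 5 in androgenetic against gynogenetic and 3 in the F test, chip B had 0, 0 (Lncenc1 gave 0.0969), 7 and 4, and the H3K27me3 list in androgenetic against fertilized embryos gave 0.0543. With the station as a block, androgenetic against gynogenetic embryos had 5 calls on chip A and 1 on chip B, the F test 1 on each chip, and chip B had 0 in both comparisons with fertilized embryos. The H3K27me3 and X-linked lists in androgenetic against fertilized embryos then gave 0.107 and 0.185, and in androgenetic against gynogenetic embryos trophectoderm gave 0.239, cholesterol synthesis 0.314, paternally expressed genes 0.327 and oxidative phosphorylation 0.379. Uncalled probe sets near background reversed with the station as a block, from −0.46 to 0.0235 for Xist and from −0.10 to 0.194 for Eif2s3y on chip B (androgenetic against fertilized), and from −0.29 to 0.295 for a further Xist probe set (androgenetic against gynogenetic).

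Without scaling, androgenetic against gynogenetic embryos had 12 calls on chip A, androgenetic against fertilized had 0 on chip B and the F test 4 on chip B. The H3K27me3 list in androgenetic against fertilized embryos gave 0.0792, cholesterol synthesis, paternally expressed genes and oxidative phosphorylation in androgenetic against gynogenetic embryos gave 0.0566, 0.165 and 0.708, Eif2s3y on chip B reversed to 0.0636 in androgenetic against fertilized embryos, and the correlation of effects on chip B was 0.531. The median change of all genes moved above 0.1 without scaling (0.158 and 0.166 on chip A for androgenetic against fertilized and gynogenetic, 0.119 on chip B for gynogenetic against fertilized), with a common trimmed mean (0.104 and −0.107 on chip A for gynogenetic against fertilized and androgenetic against gynogenetic, 0.184 and 0.228 on chip B for androgenetic and gynogenetic against fertilized) and with median centring (−0.12 on chip B, gynogenetic against fertilized). With a pseudocount of 1, chip A had 2 calls in androgenetic against fertilized embryos, a Xist probe set at 0.10 reversed to −0.0773 there, the H3K27me3 list gave 0.068, and paternally and maternally expressed genes in androgenetic against gynogenetic embryos gave 0.059 and 0.0524. With the median as pseudocount chip A had 15 calls in androgenetic against gynogenetic embryos and chip B 2 in androgenetic against fertilized, and paternally expressed genes gave 0.122 in the former.

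With no filter the H3K27me3 list in androgenetic against fertilized embryos gave 0.0826, and paternally expressed genes gave 0.051 in gynogenetic against fertilized and 0.349 in androgenetic against gynogenetic embryos. With a filter at the 50th percentile, which tests fewer probe sets, chip A had 1 call in androgenetic against fertilized embryos and 12 in the F test. A fit of 2 groups only, with fewer samples for the spread, gave 0 calls in gynogenetic against fertilized embryos on chip A, and on chip B 0 in both comparisons with fertilized embryos and 28 in androgenetic against gynogenetic. Without the intensity trend the latter had 41 calls on chip A. With array weights chip A had 40, 5 and 468 calls in androgenetic against fertilized, gynogenetic against fertilized and androgenetic against gynogenetic embryos and 296 in the F test, and chip B had 30 in the last comparison and 14 in the F test.

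With an estimated correlation camera gave 0.301 for X-linked genes, imprint maintenance, the H3K27me3 list and p53 targets and 0.59 for oocyte genes in androgenetic against fertilized embryos. In gynogenetic against fertilized embryos it gave 0.183 for paternally expressed genes, 0.217 for cholesterol synthesis, 0.27 for imprint maintenance and 0.466 for oocyte genes, and in androgenetic against gynogenetic embryos 0.175 for both imprinted lists, p53 targets and trophectoderm and 0.385 for cholesterol synthesis and oxidative phosphorylation. With fry, which does not compare a list with other genes, the androgenetic against fertilized values were 0.222 for X-linked genes, the H3K27me3 list and p53 targets, 0.249 for imprint maintenance, 0.664 for oocyte genes and 0.917, reversed, for paternally expressed genes. The gynogenetic against fertilized values were 0.0403 for maternally expressed genes, 0.0608 for paternally expressed genes, 0.0673 for cholesterol synthesis, 0.311 for imprint maintenance and 0.639 for oocyte genes. The androgenetic against gynogenetic values were 0.075 for paternally expressed genes, 0.177 for p53 targets, 0.21 for trophectoderm, 0.253 for cholesterol synthesis and 0.273 for oxidative phosphorylation. With the mean of a gene's probe sets, imprint maintenance gave 0.057 and paternally expressed genes 0.807, reversed, in androgenetic against fertilized embryos, and in androgenetic against gynogenetic embryos oxidative phosphorylation and paternally expressed genes gave 0.061 and cholesterol synthesis, maternally expressed genes and trophectoderm 0.0688. On chip B, in androgenetic against fertilized embryos X-linked genes and the H3K27me3 list gave 0.0533, in gynogenetic against fertilized embryos the H3K27me3 list gave 0.454 and paternally expressed genes 0.684, reversed, and in androgenetic against gynogenetic embryos maternally expressed genes gave 0.0868 and paternally expressed genes 0.645, reversed.

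With 1 sample left out in turn, calls on chip A ran from 0 to 3 in androgenetic against fertilized embryos, 0 to 6 in gynogenetic against fertilized, 2 to 75 in androgenetic against gynogenetic and 1 to 31 in the F test, and on chip B from 0 to 7, 0 to 2, 4 to 47 and 2 to 23, where the samples concerned are named beside the counts in the comparisons above. In androgenetic against fertilized embryos the adjusted p of the H3K27me3 list ran from 0.0154 to 0.205, of oocyte genes from 2.31e-06 to 0.552, of imprint maintenance from 0.00769 to 0.385, and of paternally expressed genes from 0.36 to 0.983 (reversed at 0.804 without androgenetic replicate 3 and 0.77 without fertilized replicate 3). In gynogenetic against fertilized embryos oocyte genes ran from 1.22e-07 to 0.873, imprint maintenance from 0.00744 to 0.0947, paternally expressed genes from 0.00552 to 0.0911 and maternally expressed genes from 0.00934 to 0.629. In androgenetic against gynogenetic embryos paternally expressed genes ran from 0.0319 to 0.451, maternally expressed genes from 0.0196 to 0.155, oxidative phosphorylation from 0.00739 to 0.478 and cholesterol synthesis from 0.00481 to 0.233. The correlation of effects ran from 0.263 (without fertilized replicate 3) to 0.673 (without fertilized replicate 1) on chip A and from 0.459 to 0.618 on chip B (without fertilized replicates 3 and 2), where simulated unchanged groups against 2 fertilized arrays gave 0.6 on each chip (0.582 to 0.617 and 0.577 to 0.614). Uncalled probe sets also reversed: in androgenetic against fertilized embryos the Xist probe sets at 0.10 and 0.65 ran from −0.627 to 0.999 and from −0.181 to 1.24 and Eif2s3y on chip B from −0.293 to 0.153, and in androgenetic against gynogenetic embryos the Xist probe set at −0.29 ran from −1.11 to 0.417. Where 2 samples of a kind were left, the spread was pooled over the 3 kinds.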

Other observations

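The hypothesis on single probe sets in this part was tested only after the results were seen.

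The X-linked shift had the same direction in all 3 samples of each uniparental kind and not only in the means. On chip A the median of X-linked genes lay below the autosomes by −0.163, −0.365 and −0.202 in the 3 androgenetic samples and above them by 0.346, 0.457 and 0.35 in the 3 gynogenetic samples, each relative to the mean of fertilized replicates 1 and 2, while fertilized replicate 3 lay at −0.0894. The chip B values were −0.257, −0.09 and −0.0823 in androgenetic and 0.15, 0.395 and 0.221 in gynogenetic samples, and 0.0287 in fertilized replicate 3. No range of single autosomes was taken per sample, so the smaller values cannot be called apart. Those of androgenetic replicates 2 and 3 on chip B are of the size of fertilized replicate 3 on chip A. The Y-linked gene Eif2s3y had a mean signal of 145 ± 196 (SD, n = 3) in androgenetic, 14.9 ± 10.8 in gynogenetic and 42.1 ± 52.4 in fertilized embryos, and its differences did not pass.

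Single genes of the developmental lists stood out when adjusted over the list alone, although their lists did not pass and the genes did not pass over all probe sets. Bmp4, a signal from the inner cell mass, was at −3.13 ± 0.70 on the log2 scale (SE, n = 3 and 3) in androgenetic against gynogenetic embryos, with an adjusted p of 0.0291 over its list and 0.184 over all probe sets. Ndrg1, a gene of differentiating trophoblast, was at −1.47 ± 0.28 (0.00682 over its list, 0.11 over all) and at −1.54 ± 0.28 in androgenetic against fertilized embryos (0.00476 over its list, 0.475 over all). Foxa2, of the primitive endoderm, was at −2.21 ± 0.36 (0.00332 over its list, 0.0645 over all), and in gynogenetic against fertilized embryos at 2.04 ± 0.36. Pou5f1, the transcription factor of pluripotent cells, was at 0.05 ± 0.17 and Cdx2, of the trophectoderm, at −0.26 ± 0.30 in androgenetic against gynogenetic embryos.

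Some autosomal genes outside the imprinted lists differed by 1 probe set while their other probe sets did not. Of 5 such genes with another probe set at or above the chip's median signal, 3 (Med1, Mfsd1 and Ttl) had no other that differed by 1 or more the same way, and 2 had one: Tpm2 at −2.95, and Gle1 at −1.04 in androgenetic against fertilized embryos only. In androgenetic against gynogenetic embryos the other probe sets of Gle1 lay between −0.287 and 1.15 where the called one was at −3.11. A strain variant under one probe set or a change of transcript end may lie behind these 3 genes, but with 5 genes the test is weak and the strains of the samples were not compared.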
